A study of Homo sapiens with 4 samples.

How the data were processed

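The series holds RNA-seq of the human lymphoma line SUP-M2 in 4 libraries, 2 labelled with a scrambled hairpin and 2 with short hairpin RNA against GOLM1. Per the labels' protocols, RNA was extracted with an RNeasy column kit and libraries were made from total RNA with a SMARTER mRNA-seq kit. The aligner, the counting tool, its strand setting and their versions are not given in the sources used here. The submitters' processing notes list the mouse builds GRCm38 and mm10, but the deposited table is human. All 58735 of its gene identifiers, with their coordinates, equal those of GENCODE 29 on GRCh38, and 0 are mouse identifiers. Symbols that a spreadsheet had turned into dates (27 genes) were replaced from GENCODE 29 by gene identifier.

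The deposited counts are whole numbers of reads per gene and library, not normalized, per the file headers. The deposited FPKM values are the authors' own, scaled by gene length and by a library total that differs from the sum of counts. They were not used in any test. The authors also deposited, per the file headers, a mean signal per group, which equals the counts divided by a size factor per library and averaged. The authors' log2 fold change and the authors' p-value and adjusted p-value of shGOLM1 against shscramble stand in the same table, with the tool not named. Values from these columns are given as the authors'.

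Library totals were 31972153 and 31608073 counts in shscramble and 30889185 and 27544171 counts in shGOLM1, with 18897, 19319, 21321 and 19122 genes detected, and 33426 genes had 0 counts in all 4 libraries. A count of 0 was given an upper limit of 3 counts per library. The shscramble libraries differed beyond sampling noise (chi-square per gene 14.4), so they were not treated as copies of one library.

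Samples were grouped by their titles. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the deposited counts, with TMM factors of 1.02, 1.05, 1.12 and 0.828, filterByExpr, no covariate, and Benjamini-Hochberg adjustment over 14166 genes. It is two-sided, with a threshold of 0.05. CPM values use the TMM-scaled totals, and log2 CPM values use a prior count of 2. Genes at 0 in one group and at least 1 CPM in the other were counted with CPM over library totals without TMM factors. Gene lists were tested with camera at a preset correlation of 0.01 where at least 3 members were tested, adjusted over the lists.

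The test, the samples, the 32 gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took GOLM1 and BCL2L1 always. It then took the genes with the largest change among those called, with both libraries of one group above both of the other and at least 5 CPM in the higher group. As none was called, it took the 5 genes with the smallest unadjusted p in each direction, which do not pass. From each list it took up to 4 members with the smallest p and a mean of at least 1 CPM. Alternatives were size factors of the DESeq2 kind, library totals alone, no filter, a filter of at least 5 CPM in 2 libraries, the replicate number as a block, each library left out, DESeq2 1.42.0, limma-voom, camera with an estimated correlation, and fry. A robust edgeR fit, edgeR's likelihood-ratio test and DESeq2 with genes at 0 in every library kept were added after seeing the data. Genes with names of clones or pseudogenes and Y-linked genes were left out of the named genes, and not every gene the rule takes is reported here. Figures were drawn with matplotlib 3.10.9.

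The procedure was tested on simulated data drawn for the same 14166 genes. At the spread of the 4-library fit of shGOLM1 against shscramble, edgeR recovered 0% of genes changed 2-fold, 1.49% of those changed 4-fold and 87.9% of those changed 16-fold, with 5 false calls. DESeq2 recovered 4.48%, 41.8% and 98.5%, with 68 false calls. At the spread between the shscramble libraries both recovered 100% at each size, with 10 false calls in edgeR and 6 in DESeq2. Camera found 20 of 20 simulated lists of 30 genes shifted 2-fold and called 0 of 20 unshifted lists. The simulated genes vary independently, which real lists need not do. Each simulated setting also gives both groups the same spread. In the data the coefficient of variation was 9.1% in the shscramble pair and 68.1% in the shGOLM1 pair. The recovery and false calls at such unequal spread were not simulated.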

Results

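RNA-seq was done on SUP-M2, an established human cell line of anaplastic large cell lymphoma, a mature T cell lymphoma that in this line carries an active ALK kinase. The 4 libraries formed 2 groups: 2 carried a scrambled short hairpin RNA (shscramble) and 2 were labelled as carrying short hairpin RNA against GOLM1 (shGOLM1). The labels do not say whether both shGOLM1 libraries carried the same hairpin sequence. GOLM1 encodes a membrane protein of the Golgi apparatus. The sample titles name hairpins, which lower a transcript, while the genotype label calls the shGOLM1 samples a knockout. The libraries held 31972153 and 31608073 counts in shscramble and 30889185 and 27544171 counts in shGOLM1. At this depth a count of 0 allows up to 3 counts, which is 0.0865 to 0.132 CPM (counts scaled to each library's total) across the libraries, and such limits cover counting error only. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

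The comparison asked what the loss of GOLM1 did to gene expression, and the title of the series ties GOLM1 to apoptosis and to BCL-XL, the anti-apoptotic protein encoded by BCL2L1. GOLM1 (ENSG00000135052, chromosome 9, 86026146 to 86100173, GRCh38) was at 212 ± 1.06 CPM (SD, n = 2) in shscramble and at 69.6 ± 0.0515 CPM (SD, n = 2) in shGOLM1. It was 3.05-fold lower, and both shGOLM1 libraries lay below both shscramble libraries. BCL2L1 (ENSG00000171552, chromosome 20, 31664452 to 31723989) was at 24.6 ± 3.51 CPM (SD, n = 2) in shscramble and at 16.8 ± 1.78 CPM (SD, n = 2) in shGOLM1, again with both shGOLM1 libraries lower. The log2 fold change of GOLM1 was -1.61 (SE 0.27), with an adjusted p of 0.42 in edgeR's quasi-likelihood test and 0.0502 in DESeq2. The authors' deposited table gives -1.64 with an adjusted p of 0.0531. The log2 fold change of BCL2L1 was -0.55 (SE 0.33), with an adjusted p of 0.53 in edgeR and 0.74 in DESeq2, and the authors' deposited table gives -0.58 with an adjusted p of 0.75. With a single shGOLM1 library against both shscramble libraries, GOLM1 passed edgeR's test with either one, at adjusted p of 6.56e-10 without replicate 2 and 3.38e-09 without replicate 1, in a range up to 1 over its alternatives. BCL2L1 also passed with either one, at adjusted p of 0.0208 and 0.0015 in edgeR, in a range up to 1. These fits assume that the lone library varies like the shscramble pair, and they compare libraries, not conditions.

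**Figure D1:**
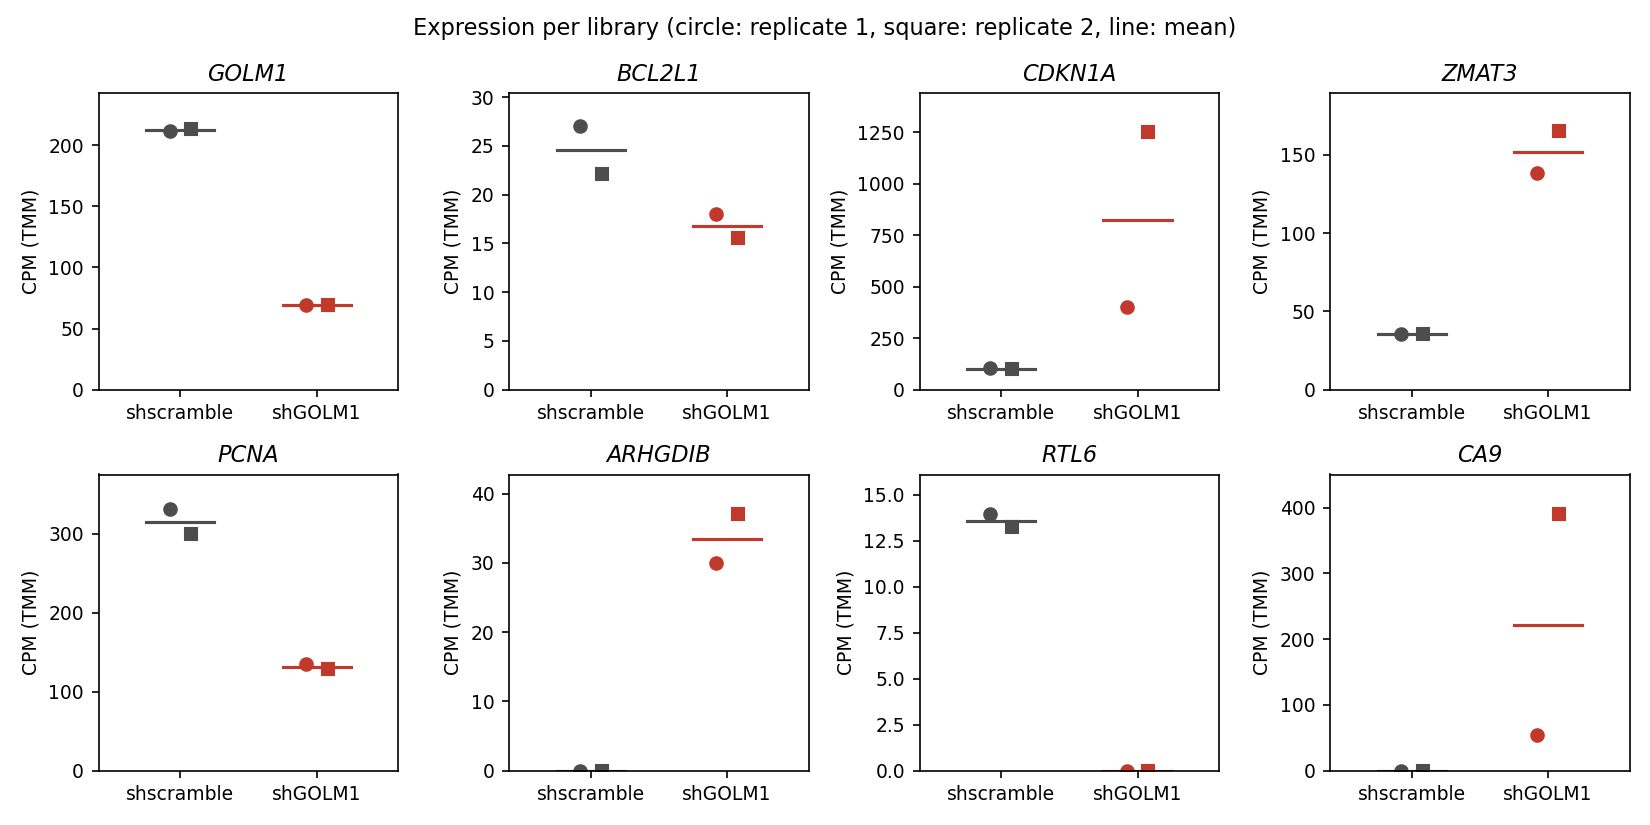
CPM with TMM scaling (y axis, linear from 0) in each of the 4 libraries for 8 genes, with circles for replicate 1, squares for replicate 2 and a line at each group mean. GOLM1 sits near 212 CPM in shscramble and near 69.6 CPM in shGOLM1, while CDKN1A lies at 402 and 1249 CPM and CA9 at 54.1 and 390 CPM in the 2 shGOLM1 libraries.

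The genes with the smallest unadjusted p were largely genes that one group barely expressed, and none of them passed the adjusted threshold in edgeR as planned. The 10 named here all passed in DESeq2, with adjusted p from 7.36e-19 to 6.0e-08, and in edgeR with no filter on low counts, with adjusted p from 9.73e-06 to 0.00147, while limma-voom passed 0 of them. Over all alternatives their adjusted p ran from 1.36e-23 in edgeR's likelihood-ratio test to 0.489 in edgeR with library totals alone. LAPTM5, which encodes a lysosomal membrane protein of blood cells, was at 1.32 ± 0.132 CPM in shscramble and 66.8 ± 11 CPM in shGOLM1 (SD, n = 2 each). NECTIN4, an adhesion molecule, was at 0.122 ± 0.0446 against 21.7 ± 3.65 CPM. MACROD2 was at 0.622 ± 0.0989 against 35.9 ± 16.1 CPM, and the noncoding gene CERNA2 at 0.121 ± 0.00164 against 17.9 ± 8.6 CPM. ARHGDIB (chromosome 12, 14942017 to 14961728) had 0 counts in both shscramble libraries and 1039 and 843 counts in the shGOLM1 libraries, so it was at least 368-fold higher, with the floor set at 3 counts per library. In the other direction IL18RAP, a subunit of the interleukin 18 receptor, was at 27.5 ± 0.723 CPM in shscramble and 1.83 ± 0.103 CPM in shGOLM1. The noncoding gene ARLNC1 was at 14 ± 0.133 against 0.429 ± 0.0766 CPM, and SLC8A1-AS1 at 18.1 ± 1.69 against 0.408 ± 0.169 CPM. SLC8A1-AS1 is antisense to SLC8A1, and since the strand used in counting is not given in the sources used here, its reads are not assigned with certainty. RTL6 (chromosome 22, 44492572 to 44498298) had 455 and 440 counts in shscramble and 0 in both shGOLM1 libraries, at least 124-fold lower. RMND5A had 993 counts over the shscramble pair and 1 count over the shGOLM1 pair, a ratio of 866 with a 95% counting interval from 155 to 34228.

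Over all genes, edgeR's quasi-likelihood test called 0 of 14166 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.42. At an unadjusted p under 0.05 there were 1668 genes, 1161 higher and 507 lower in shGOLM1, where chance gives 708. DESeq2 called 514 genes higher and 40 lower, limma-voom called 0, and edgeR's likelihood-ratio test, chosen after seeing the data, called 434 higher and 62 lower. The authors' deposited table has 501 genes higher and 39 lower among 23642 with a test, and 118 of the 501 have at most 2 counts in each shscramble library. The groups did not overlap for 51.7% of the tested genes, 3566 higher and 3753 lower in shGOLM1, where chance gives 33.3%.

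The shGOLM1 libraries differed from each other far more than the shscramble libraries did. The coefficient of variation between replicates was 9.1% in the shscramble pair and 68.1% in the shGOLM1 pair. Across genes, log2 CPM correlated at 0.996 between the shscramble libraries and at 0.881 between the shGOLM1 libraries, and genes are not independent replicates. With shscramble replicates 1 and 2, shGOLM1 replicate 1 correlated at 0.964 and 0.969, and shGOLM1 replicate 2 at 0.876 and 0.874. By this measure shGOLM1 replicate 1 was closer to the shscramble libraries than to shGOLM1 replicate 2. In shGOLM1 replicate 2, mitochondrially encoded genes took 0.456% of counts, against 1.95% in replicate 1 and 2.38% and 2.24% in shscramble. Ribosomal-protein genes took 16.4% of its counts, against 7.55% in replicate 1 and 9.91% and 8.44% in shscramble. Without shGOLM1 replicate 2, edgeR called 3087 genes higher and 3634 lower, and without shGOLM1 replicate 1 it called 5078 higher and 5212 lower. Without shscramble replicate 1 it called 17 higher and 5 lower, and without shscramble replicate 2 it called 16 and 4.

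Of the 32 gene lists fixed before the data were examined, 18 passed camera at an adjusted p under 0.05 with its preset correlation, 12 higher and 6 lower in shGOLM1. With an estimated correlation 0 lists passed, and with fry 0 passed. That correlation was -0.024 for the p53 targets and -0.0274 for the FOXO list. It was 0.983 for glycolysis and hypoxia, 0.977 for mitochondrially encoded genes and 0.99 for ribosomal proteins. For lists correlated this strongly, camera's adjusted p at the preset 0.01 is too small. For a list below the preset 0.01, correlation among its members is not what removed the call. With an estimated correlation, camera takes its degrees of freedom from the few libraries and not from the genes. Almost no list can then pass after adjustment. Camera's adjusted p was 0.559 for the p53 targets and also for DNA replication genes, whose correlation was 0.229. The loss of all calls in that setting therefore does not separate the lists. No member of any list passed edgeR's test over all genes. Some genes stand in more than one list, among them BBC3, BNIP3, FAS, SESN2, TNFAIP3, CXCL8, CREB3L2, HSPE1 and MDM2.

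Targets of p53, the damage-responsive transcription factor, were higher in shGOLM1 by camera (adjusted p = 2.99e-07, with 23 members tested), with adjusted p = 0.559 with an estimated correlation. The median log2 difference from the shscramble mean was 0.93 in shGOLM1 replicate 1 and 1.01 in replicate 2. In the shGOLM1 libraries taken alone, 15 members were higher in both and 0 were lower in both by edgeR, while 2 were lower in replicate 2. Adjusted over the list alone, 4 members passed in edgeR: TP53INP1, ZMAT3, GDF15 and CDKN1A. CDKN1A, which encodes the cell cycle inhibitor p21, was at 101 ± 3.7 CPM in shscramble and 825 ± 599 CPM in shGOLM1 (SD, n = 2 each). ZMAT3 was at 35.5 ± 0.229 against 152 ± 19.3 CPM, TP53INP1 at 2.23 ± 0.266 against 33.3 ± 13.7 CPM, and the secreted stress factor GDF15 at 0.624 ± 0.287 against 33.2 ± 33.9 CPM. MDM2, which encodes the ubiquitin ligase of p53, was at 146 and 165 CPM in shscramble and at 921 and 285 CPM in shGOLM1 replicates 1 and 2.

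Genes of glycolysis and hypoxia were higher by camera (adjusted p = 1.91e-07, 28 members), with adjusted p = 0.603 with an estimated correlation. Their median log2 difference was 0.45 in shGOLM1 replicate 1 and 2.23 in replicate 2, the library with the low mitochondrial share. CA9, a carbonic anhydrase induced by hypoxia, had 0 counts in shscramble and 54.1 and 390 CPM in shGOLM1 replicates 1 and 2, at least 2438-fold higher and at least 594-fold without replicate 2. SLC2A1, the glucose transporter GLUT1, was at 113 ± 3.55 against 527 ± 318 CPM, and PFKFB4 at 14.9 ± 0.0301 against 150 ± 120 CPM (SD, n = 2 each). Targets of ATF4 in the integrated stress response followed the same order, with medians of 0.33 and 2.43 in replicates 1 and 2. Their camera adjusted p was 0.000293, with adjusted p = 0.568 with an estimated correlation, and 0.112 in replicate 1 taken alone. DDIT4, an inhibitor of mTOR signalling, was at 17.4 and 19.4 CPM in shscramble and at 86.1 and 1879 CPM in shGOLM1. STC2 was at 40.9 ± 1.71 against 174 ± 119 CPM. Targets of NF-kB had medians of 0.32 and 2.12 (camera adjusted p = 0.000367, and adjusted p = 0.568 with an estimated correlation), with TNFAIP3 at 25.5 ± 0.301 against 102 ± 52.1 CPM, and did not pass camera in replicate 1 taken alone (adjusted p = 0.176). Replication-dependent histones had medians of 0.31 and 2.00 (camera adjusted p = 0.00881, and adjusted p = 0.568 with an estimated correlation). They did not pass camera in replicate 1 taken alone (adjusted p = 0.52) or without shscramble replicate 2 (adjusted p = 0.0558). Histone genes took 0.00867% of counts in shGOLM1 replicate 1 and 0.0264% in replicate 2, against 0.00905% and 0.00805% in shscramble. The list thus rests on a very small share of reads, raised in replicate 2, and is not read as a sign of more DNA replication. Histone reads can be shared between near-identical copies, so single histone genes are uncertain.

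Genes of COPI, COPII and secretory transport were higher by camera (adjusted p = 0.000238, 31 members), with adjusted p = 0.559 with an estimated correlation. Their medians were 0.46 and 0.89 in shGOLM1 replicates 1 and 2, and 13 members were higher in both libraries taken alone. SEC24D, a COPII coat subunit, was at 52.6 ± 2.83 against 121 ± 28.2 CPM, and KDELR2, a receptor that returns proteins to the endoplasmic reticulum, at 182 ± 7.25 against 405 ± 105 CPM (SD, n = 2 each). The unfolded protein response had medians of 0.12 and 0.61 (camera adjusted p = 0.015, and adjusted p = 0.559 with an estimated correlation). It did not pass camera without shGOLM1 replicate 2 (adjusted p = 0.0638) or without shscramble replicate 2 (adjusted p = 0.104). CANX, the chaperone calnexin, was at 1290 ± 27.2 against 3265 ± 372 CPM. FOXO targets and AKT-mTOR feedback genes had medians of 0.33 and 0.34 (camera adjusted p = 0.015, and adjusted p = 0.559 with an estimated correlation), with FOXO3 at 7.5 ± 0.359 against 19.3 ± 1.66 CPM. The FOXO list did not pass camera in replicate 2 taken alone (adjusted p = 0.267), where 11 members were higher and 8 lower by edgeR, and 5 members went in opposite directions in the libraries. Nor did it pass without shscramble replicate 1 (camera adjusted p = 0.0667). Immediate-early and AP-1 genes had medians of 0.37 and 0.66 (camera adjusted p = 0.0211, and adjusted p = 0.568 with an estimated correlation), with FOSB at 0.425 ± 0.0487 against 4.43 ± 2.8 CPM, and did not pass camera in replicate 1 taken alone (adjusted p = 0.0652).

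Ribosomal proteins passed camera as higher (adjusted p = 0.015, 60 members), with adjusted p = 0.868 with an estimated correlation, but the shGOLM1 libraries differed in sign. The median was -0.40 in replicate 1 and 1.17 in replicate 2, and 40 members passed edgeR in opposite directions in the libraries taken alone. In camera the list passed as lower in replicate 1 alone (adjusted p = 7.41e-07) and did not pass without shscramble replicate 2 (adjusted p = 0.405). Without replicate 2, RPS23 and RPL28 had log2 fold changes of -0.12 and -0.10. Ribosomal-protein reads can be shared with processed pseudogenes, so single members are uncertain.

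DNA replication genes driven by E2F were lower in shGOLM1 by camera (adjusted p = 5.96e-09, 39 members), with adjusted p = 0.559 with an estimated correlation. Their median log2 difference was -0.59 in shGOLM1 replicate 1 and -1.55 in replicate 2. In the libraries taken alone, 27 members were lower in both and 0 were higher in both by edgeR. PCNA, the sliding clamp of DNA polymerases, was at 315 ± 22.3 against 132 ± 4.86 CPM, CDC45 at 86.2 ± 5.76 against 32.5 ± 10.8 CPM and GINS2 at 43.2 ± 4.08 against 15.5 ± 3.65 CPM (SD, n = 2 each). Mitosis genes had medians of -0.48 and -0.20 (camera adjusted p = 0.0141, and adjusted p = 0.559 with an estimated correlation), and 12 were lower in both libraries while 8 went in opposite directions. The mitosis call rested on replicate 1 (camera adjusted p = 1.94e-06 alone) and was lost in replicate 2 alone (camera adjusted p = 0.544), where 12 members were higher and 15 lower by edgeR. AURKA, a mitotic kinase, was at 208 ± 4.87 against 89.6 ± 18.7 CPM.

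Ribosome biogenesis genes driven by MYC were lower by camera (adjusted p = 1.52e-07, 33 members), with adjusted p = 0.559 with an estimated correlation. Their medians were -0.52 and -2.20 in shGOLM1 replicates 1 and 2, and NOP58 was at 297 ± 5.77 against 120 ± 43.2 CPM. Mitochondrially encoded genes had medians of -0.55 and -2.49 (camera adjusted p = 9.52e-06, and adjusted p = 0.568 with an estimated correlation), and MT-ND3 was at 586 ± 198 against 76.5 ± 66.7 CPM. Heat shock genes had medians of -0.65 and -0.98 (camera adjusted p = 0.00157, and adjusted p = 0.559 with an estimated correlation). AHSA1, an activator of the chaperone HSP90, was at 244 ± 20.2 against 91.4 ± 18.5 CPM, and the chaperonin gene HSPE1 at 74.9 ± 0.539 against 37.1 ± 0.201 CPM. Genes of the proteasome and ubiquitin system had medians of -0.45 and -0.41 (camera adjusted p = 0.0198, and adjusted p = 0.559 with an estimated correlation). Of 34 members, 19 lay lower in both shGOLM1 libraries than in both shscramble libraries, and 2 lay higher. PSMD12 was at 375 ± 3.18 against 203 ± 37 CPM. The 2 members with the smallest p, OTUD1 and MDM2, were higher, with OTUD1 at 7.6 ± 1.035 against 19.9 ± 3.86 CPM.

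**Figure D2:**
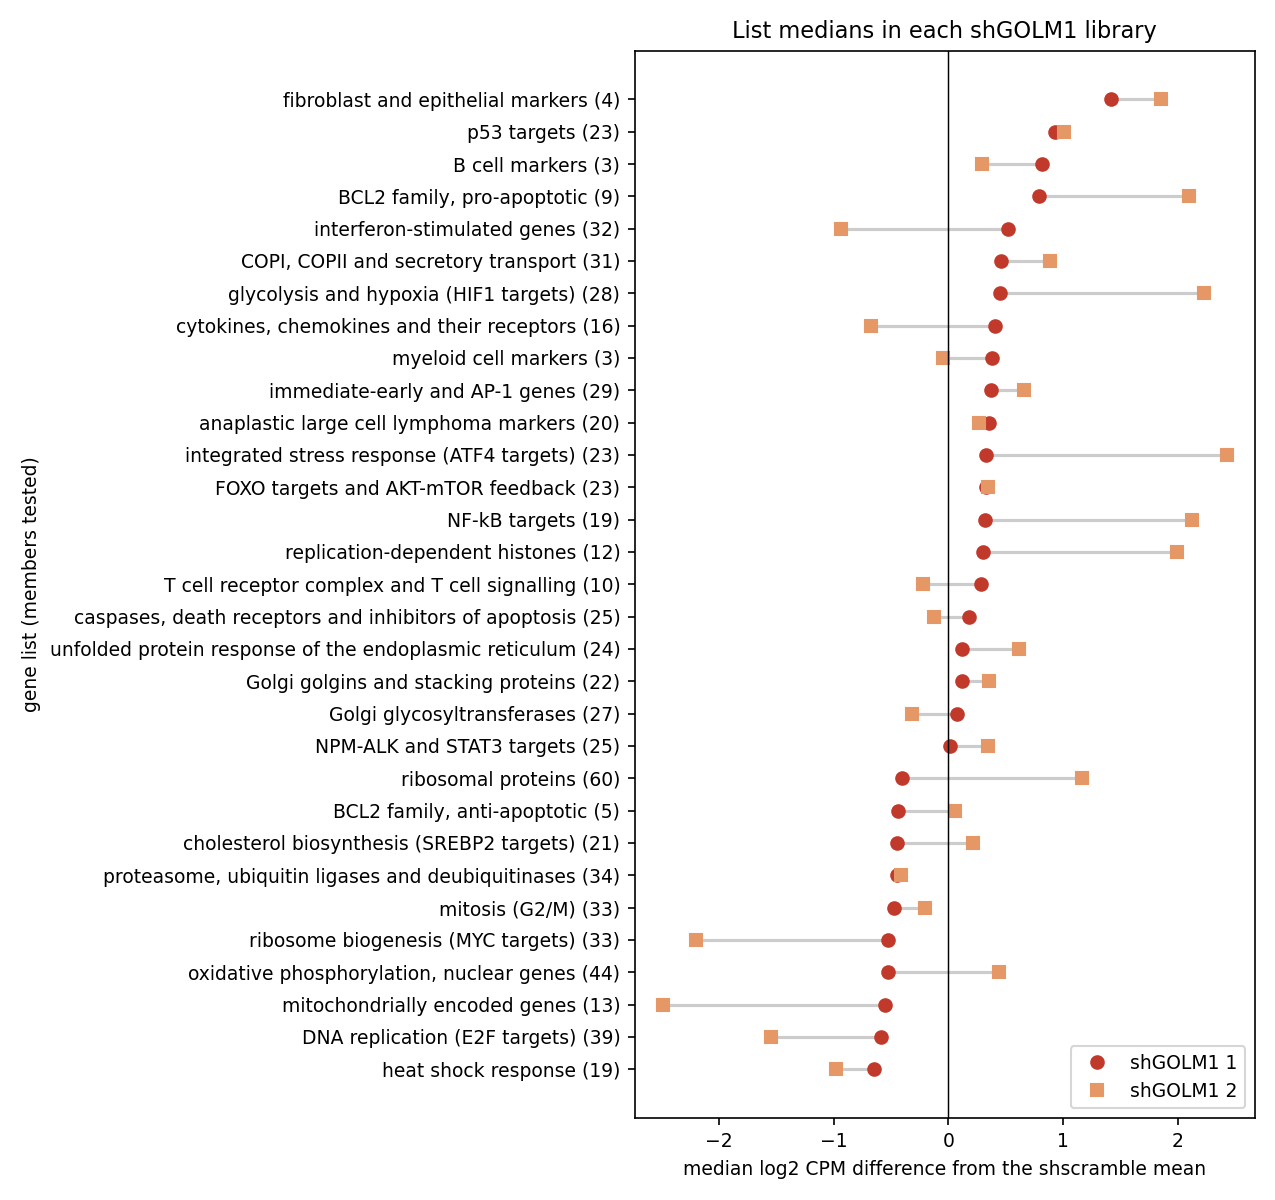
Median log2 CPM difference from the shscramble mean (x axis) of each gene list with a test (y axis, members tested in parentheses), with a circle for shGOLM1 replicate 1 and a square for replicate 2. The p53 targets lie at 0.93 and 1.01, while glycolysis and hypoxia genes lie at 0.45 and 2.23, and ribosomal proteins at -0.40 and 1.17.

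Among the apoptosis genes, pro-apoptotic BCL2 family members were higher by camera (adjusted p = 0.015, 9 members), with adjusted p = 0.559 with an estimated correlation and medians of 0.79 and 2.10 in shGOLM1 replicates 1 and 2. BBC3, which encodes PUMA, was at 3.49 ± 0.253 against 33.2 ± 33.9 CPM, and BMF at 0.213 ± 0.00287 against 1.42 ± 0.149 CPM (SD, n = 2 each). BNIP3L was at 29.1 ± 0.673 against 287 ± 276 CPM, and BNIP3 at 27.6 ± 3.64 against 121 ± 103 CPM. Of the 9 members, 6 lay higher in both shGOLM1 libraries than in both shscramble libraries, and 1 lay lower. BNIP3L was at 92.4 and 482.5 CPM in shGOLM1 replicates 1 and 2, the same order as the glycolysis and hypoxia list. BNIP3 also stands in the glycolysis and hypoxia list, and its value of 0.79 was the pro-apoptotic median in replicate 1. The pro-apoptotic list was not tested without BNIP3 or BNIP3L. Anti-apoptotic BCL2 family members did not pass (camera adjusted p = 0.77, 5 members). Their median log2 fold change of 0.15 was above 0, while the camera direction was lower. Beside BCL2L1, MCL1 was at 604 ± 17.4 against 708 ± 151 CPM and BCL2 at 13.1 ± 0.929 against 14.6 ± 2.24 CPM. Caspases, death receptors and inhibitors of apoptosis did not pass (camera adjusted p = 0.66, 25 members), with 6 members higher and 6 lower in both libraries taken alone. FAS, a death receptor, was at 12.5 ± 1.57 against 38.1 ± 19.7 CPM. It overlaps ACTA2 on the other strand, so reads in the overlap are not assigned with certainty.

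The lists for the lymphoma itself did not pass camera over the 4 libraries. Targets of the NPM-ALK fusion and STAT3 had an adjusted p of 0.93 in camera (25 members). Their median log2 fold change of 0.22 was above 0, while the camera direction was lower. BATF, an AP-1 factor of T cells, was at 77.7 ± 4.27 against 35.7 ± 1.91 CPM, and SOCS3, a feedback inhibitor of STAT3 signalling, at 343 ± 9.12 against 556 ± 55.3 CPM (SD, n = 2 each). Anaplastic large cell lymphoma markers had a camera adjusted p of 0.34 (20 members) and medians of 0.35 and 0.27 in shGOLM1 replicates 1 and 2. In replicate 1 alone they passed camera as higher (adjusted p = 0.00381, 10 members higher and 4 lower by edgeR), and in replicate 2 alone they did not (adjusted p = 0.756, 9 higher and 8 lower). PRF1, the pore-forming protein of cytotoxic cells, was the member that passed over the list alone in edgeR, at 2.81 ± 0.145 against 383 ± 337 CPM. ALK was at 328 ± 17 against 249 ± 111 CPM, and TNFRSF8, which encodes the diagnostic marker CD30, at 624 ± 14.4 against 314 ± 318 CPM. ALK and TNFRSF8 were chosen after their values were seen. T cell receptor and signalling genes had a camera adjusted p of 0.77 (10 members).

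Few markers of other cell types were expressed highly enough to be tested. Fibroblast and epithelial markers passed camera as higher (adjusted p = 0.0238, 4 members), with adjusted p = 0.559 with an estimated correlation. The list did not pass camera in replicate 1 alone (adjusted p = 0.0652), in replicate 2 alone (adjusted p = 0.209) or without shscramble replicate 1 (adjusted p = 0.119). LUM, a fibroblast proteoglycan, had 0 counts in shscramble and 0.923 and 1.71 CPM in shGOLM1, at least 14.5-fold higher, and ACTA2 was at 4.25 ± 0.1 against 12.4 ± 4.54 CPM (SD, n = 2 each). Both passed over the list alone in edgeR. ACTA2 overlaps FAS, which lies on the other strand and was also higher. As the strand used in counting is not given, reads in the overlap are not assigned with certainty. B cell markers (camera adjusted p = 0.27, 3 members) and myeloid markers (camera adjusted p = 0.52, 3 members) did not pass. The B cell list passed as higher in replicate 1 alone (camera adjusted p = 0.0172, 3 of 3 members higher by edgeR) but not in replicate 2 alone (adjusted p = 0.915). EBF1, a B cell transcription factor, was at 30.6 and 31.5 CPM in shscramble and at 54.6 and 0.791 CPM in shGOLM1 replicates 1 and 2. POU2AF1, a B cell coactivator, passed over its list alone in edgeR, at 0.758 ± 0.161 against 4.13 ± 0.119 CPM, and CSF1R, a growth factor receptor of myeloid cells, was at 238 ± 5.05 against 270 ± 55.6 CPM. Of the erythroid and platelet markers only 1 was tested, HBG2, with 0 counts in shscramble and 0.404 and 0.879 CPM in shGOLM1, and the list had no camera test.

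The remaining lists did not pass camera over the 4 libraries, while 3 of them passed in shGOLM1 replicate 1 taken alone and 0 in replicate 2. Golgi golgins and stacking proteins had an adjusted p of 0.66 in camera (22 members), with medians of 0.12 and 0.35 in shGOLM1 replicates 1 and 2. GOLGA4 was lower, at 160 ± 7.56 against 92.2 ± 20.2 CPM (SD, n = 2 each). ACBD3 was higher, at 143 ± 1.76 against 355 ± 141 CPM, and GOLGA2 and BLZF1 were higher too. Golgi glycosyltransferases had a camera adjusted p of 0.996 (27 members), with GALNT3 at 8.66 ± 0.804 against 29.5 ± 7.89 CPM. Nuclear genes of oxidative phosphorylation had a camera adjusted p of 0.61 (44 members), with medians of -0.52 and 0.45 in shGOLM1 replicates 1 and 2. They passed as lower in replicate 1 alone (camera adjusted p = 7.04e-07, 33 members lower and 1 higher by edgeR), and in replicate 2 alone the direction was higher (camera adjusted p = 0.0538). Cholesterol biosynthesis genes had a camera adjusted p of 0.67 (21 members), with medians of -0.44 and 0.22, and passed as lower in replicate 1 alone (camera adjusted p = 0.0017, 14 lower and 2 higher by edgeR) but not in replicate 2 alone (camera adjusted p = 0.364). Interferon-stimulated genes had a camera adjusted p of 0.66 (32 members), with medians of 0.52 and -0.93, and passed as higher in replicate 1 alone (camera adjusted p = 0.00193, 15 higher and 2 lower by edgeR) but not in replicate 2 alone (camera adjusted p = 0.407). Cytokines, chemokines and their receptors had a camera adjusted p of 0.77 (16 members), with medians of 0.40 and -0.67.

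**Figure D3:**
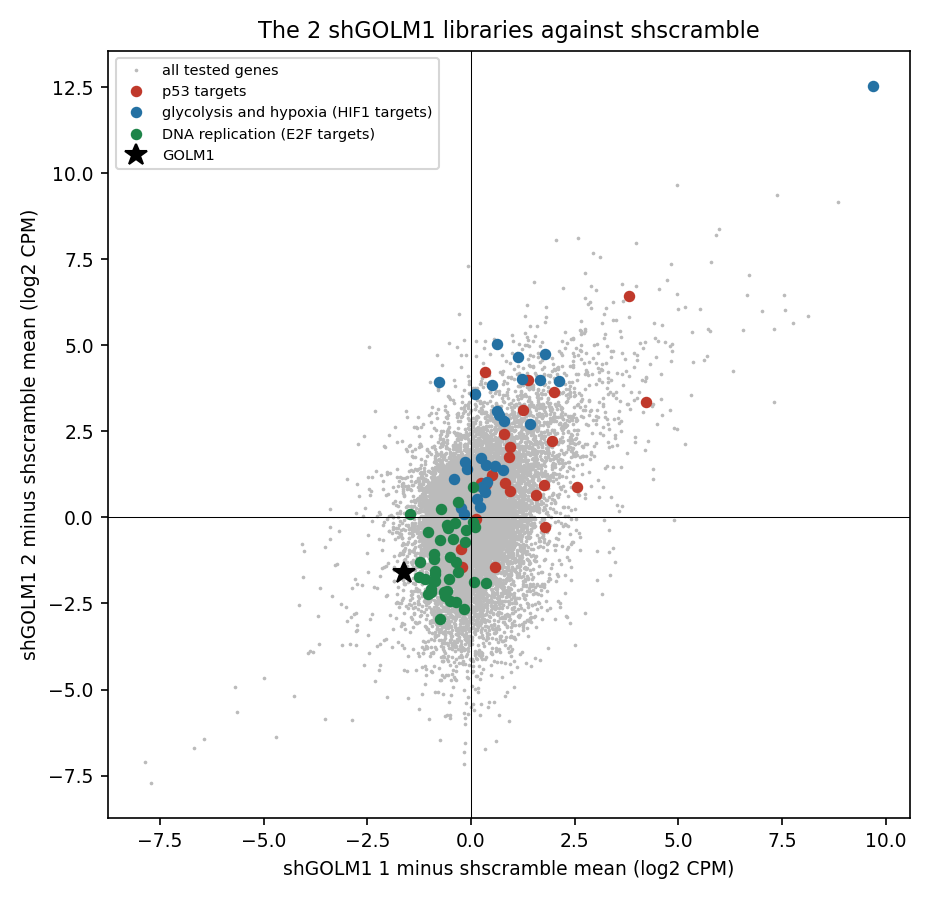
Log2 CPM difference from the shscramble mean for shGOLM1 replicate 1 (x axis) and shGOLM1 replicate 2 (y axis), with a grey point for each of the 14166 tested genes and colours for 3 lists. GOLM1 (star) lies at a similar negative value on both axes, and the correlation across genes was 0.437.

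The shGOLM1 libraries were also compared with each other through their calls against the same shscramble libraries. Of 14377 genes tested in both fits, 1383 were higher and 1995 lower in both by edgeR, and 1604 were called in opposite directions. Independent lists of the same sizes would share 894 and 1317 genes, with 2172 in opposite directions. Simulated libraries with no effect had 0 called genes each, so their 0 shared calls were fixed and give no reference for the overlap. The log2 differences correlated at 0.437 across genes, against 0.0301 in the simulation, with a covariance of 0.71 against 0.00277. With a different shscramble library for each shGOLM1 library, the correlation was 0.356 with same-numbered libraries and 0.426 with the numbers crossed, and the covariance with same-numbered libraries was 0.621. The simulation gave a correlation of -0.350 and a covariance of -0.0511 for same-numbered libraries, below 0 because its means come from the average of the shscramble pair. No shscramble library is shared in such a split, so the covariance of 0.621 that remained does not come from the noise of a shared library. The shared calls have no such split, since it leaves a single shscramble library on each side. Part of the excess in shared calls may therefore still come from the shared libraries.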

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

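The robust edgeR fit, the likelihood-ratio test and DESeq2 with genes at 0 in every library kept were chosen only after the result was seen. The count of called genes was 0 in edgeR as reported, with size factors of the DESeq2 kind, with library totals alone, with at least 5 CPM in 2 libraries, in the robust fit and in limma-voom. It was 192 with no filter on low counts (175 higher, 17 lower), 554 in DESeq2 (514 and 40), 549 in DESeq2 with genes at 0 kept (510 and 39), and 496 in the likelihood-ratio test (434 and 62). All of these calls were at least 2-fold. With a library left out, the count ranged from 20 to 10290 (16 to 5078 higher, 4 to 5212 lower), and the count of at least 2-fold changes from 20 to 6687. The high counts come from fits that keep a single shGOLM1 library, whose spread is then taken from the shscramble pair. The cause of the differences between tools was not tested. The replicate numbers are shared across groups with no statement that they pair samples, and the deviations of same-numbered libraries correlated at -0.098 across genes over 2 pairs. With the replicate block edgeR called 203 genes (169 higher, 34 lower).

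GOLM1 stayed lower in every alternative run, at -1.66 to -1.63 with a library left out, and it passed only without a shGOLM1 library and in the likelihood-ratio test (-1.61, adjusted p 0.0111, in a range from 6.56e-10 to 1). BCL2L1 stayed lower in every alternative run, at -0.74 to -0.44 with a library left out, and passed only without a shGOLM1 library. Lists past the threshold numbered 18 as reported, 0 with an estimated correlation and 0 with fry (0 higher and 0 lower in each), and those higher numbered 7 with no filter against 12. Of 94 other genes recomputed under the alternatives, at least 6 changed sign with a shGOLM1 library left out. The log2 fold change ranged from -0.023 to 0.38 for MCL1, -0.063 to 0.28 for BCL2, -0.62 to 0.0046 for BCL2L2, -5.34 to 0.80 for EBF1, -0.10 to 1.39 for RPL28 and -0.12 to 1.66 for RPS23. CSF1R also went from 0.18 to -0.094 without shGOLM1 replicate 1, and MSMO1 from 2.07 to -0.35 without shGOLM1 replicate 2. The cause was not tested. Depth limits genes near 0 counts, where 3 counts in a library are 0.0865 to 0.132 CPM.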

Other observations

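The tests of another culture, of mixed-in cells, of other short-lived families and of the reduced p53 list were chosen only after the result was seen, and so were the rules that select the genes in the next paragraphs.

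Some genes switched between no reads and clear expression. With 0 counts in both shscramble libraries and at least 1 CPM in both shGOLM1 libraries there were 22 genes (CPM over library totals without TMM factors in this count), and with 0 counts in both shGOLM1 libraries and at least 1 CPM in both shscramble libraries there were 4. The other splits of the libraries into pairs gave 0. Beside CA9 and ARHGDIB, the 22 included TREM1, a receptor of myeloid cells, at 1.96 and 52.9 CPM in shGOLM1 replicates 1 and 2, at least 301-fold higher on average but at least 21.5-fold without replicate 2. MAGEH1 was at 4.04 and 21.7 CPM, at least 141-fold higher and at least 44.3-fold without replicate 2. ALOX5AP, needed for leukotriene synthesis, was at 1.79 and 10.7 CPM, at least 68.4-fold higher and at least 19.6-fold without replicate 2. GLI3, a transcription factor of hedgehog signalling, was at 12.4 and 4.22 CPM, at least 91.2-fold higher and at least 46.3-fold without replicate 1. The 4 were RTL6, RIC8B (at least 60.6-fold lower), GLB1L2 (at least 51.4-fold lower) and TCEAL3 (at least 29.4-fold lower).

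In shGOLM1 replicate 2 alone, 121 genes reached at least 100 CPM and lay at least 4-fold above every other library, and 180 genes with at least 50 CPM in every other library lay at least 4-fold below. HILPDA, a lipid droplet protein induced by hypoxia, was at 2323 CPM, 157-fold above the next library. PPP1R15A and DDIT3, which act in the integrated stress response, were 27.9-fold and 24.5-fold above the next, and GADD45B was 60.9-fold above. Among the lower genes, HPS6 was 62.9-fold and the cytokine gene IL10 31.4-fold below the nearest other library.

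shGOLM1 replicate 2 stood apart from replicate 1, with an SD of 1.54 across 14159 genes for their log2 difference. A trend on GC content and length is argued against as the main cause, since removing it lowered that SD by 1.37%. Whether replicate 2 came from another culture stays open: of 39 genes at 0 counts in replicate 1 and at least 1 CPM in both shscramble libraries, or the reverse, 26 (66.7%) were in the state of replicate 1 in replicate 2, and 35 (89.7%) if any count is taken as on. Transcripts of zinc finger (ZNF) genes, many of them short-lived, had a median difference of -0.94 over 261 genes, below all 10000 random lists matched on expression (95% of which lay between -0.29 and 0.15), and of -0.77 after GC and length. Immediate-early and AP-1 genes and NF-kB targets, which also hold short-lived transcripts, went the other way (medians of 0.59 over 29 and 1.52 over 19 genes, with IER3 31.2-fold and NFKBIA 20.5-fold above the next library), so a general loss of such transcripts stays open, as loss and induction were not separated, and handling of the culture or RNA, the degree of response and a different hairpin in replicate 2, which the labels leave open, were not tested.

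For the genes that switched on or off, cells of another type mixed into the shGOLM1 cultures cannot remove a transcript, and 4 genes with reads in shscramble had 0 counts in both shGOLM1 libraries. Over 53 markers of fibroblasts, epithelium, B cells, myeloid cells, erythroid cells and platelets with little or no signal in shscramble (LUM, one of the 22, left out), the highest median of a type was 0.167 CPM with 3 counts as the floor, against a median of 2.54 CPM for the genes that switched on, and COL1A2, HBB, IGKC, S100A8 and KRT5 had 0 counts in both shGOLM1 libraries. This argues against these types only, and markers with more signal in shscramble, among them ACTA2, POU2AF1 and KRT8, which were higher on average in shGOLM1, were not used. Loss of a segment with several genes is argued against, as 0% of 19 expressed neighbours within 500 kb of the 4 genes were at 0 in shGOLM1. Deletion or silencing of single genes stays open, and the pattern may reflect the hairpin or a difference between sublines that existed before it, which the design does not separate.

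The median of the p53 targets was higher in both shGOLM1 libraries. Of 23 members, 18 lay higher in both shGOLM1 libraries than in both shscramble libraries, and 2 lay lower. For the p53 targets, camera with an estimated correlation gave an adjusted p of 0.559 and fry gave an adjusted p of 0.105. With so few libraries almost no list can pass camera in that setting, so this neither backs nor removes the p53 targets as a list, and the call rests on the preset correlation. After removing a trend on GC and length their median log2 difference was 1.07 in the lower and 1.14 in the higher of the libraries, so that trend is not the whole cause. Without 6 members that ATF4 or CHOP also induce, the medians over 17 members were 0.929 and 0.987, so those 6 members alone do not account for the shift. The 17 were not filtered for targets of hypoxia, FOXO or NF-kB, so a wider stress response stays open. A p53 response in the shGOLM1 cells may be considered as a hypothesis, found and tested on the same data. Whether it follows from GOLM1, from the hairpin or from the state of these cultures was not tested.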
